A study of Homo sapiens with 105 samples.

How the data were processed

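Single cells of 3 lines named MCF7, MCF7M1 and MCF7TR were profiled by single-cell DNA sequencing. MCF7 is an established human breast cancer epithelial line, and the series presents the 3 lines as a model of cancer cells that tolerate drugs. Per the labels' protocols, genomic DNA of each isolated cell was amplified with the ResolveDNA whole-genome amplification kit, and libraries were made with the matching kit. Per the submitters' processing notes, BWA and the human genome build hg19 were used. The copy-number caller's settings, the BWA version and the read depth of each cell are not given in the sources used here.

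The authors' deposited table held 5602 bins of 500 kb, of which 5261 lay on autosomes, 300 on chromosome X and 41 on chromosome Y, and 105 columns with 1 cell each. Each cell's value in a bin was a whole copy number from 0 to 3, or missing. What the copy numbers are relative to is not given in the sources used here, so a value of 2 is a called state and not a measured ploidy. The authors deposited the GC content of each bin as a fraction of its bases. The mappability was deposited as a score between 0 and 1 whose definition is not given in the sources used here. Both were used to match bins of other autosomes to the lost regions and to relate the call rate to bin properties, and they entered no comparison of lines. All positions are on hg19 and are counted from 1.

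Each column was matched to its cell by the title, and the line was taken from the cell line label. The labels gave 33 MCF7, 34 MCF7M1 and 38 MCF7TR cells, whereas the series' design text gives 33, 33 and 39. The titles split each line into 2 sets of cells, which were CL1 and CL2 for MCF7, CL5 and CL6 for MCF7M1, and CL3 and CL4 for MCF7TR. What a set stands for is not stated. The index numbers in the column names did not repeat within CL1 to CL3 (50 columns) or within CL4 to CL6 (55 columns), but only 60 different numbers occurred over all 105 columns. The cells were therefore taken to come from 2 index series, with every MCF7 cell in the first, every MCF7M1 cell in the second and MCF7TR cells in both. The contrast of MCF7M1 with MCF7 thus coincides with the contrast of the index series.

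Each cell was 1 sample in the labels and no separate cultures were named, so a line counted as 1 sample. No significance test was run between lines, and no standard error was made from cells. SDs describe the spread over cells, and for distances the spread over pairs of cells. Shares of cells carry 95% exact Clopper-Pearson intervals, which cover counting error only. For 0 of 38 cells the share that 3 cells would give is printed as well. A cell with no called bin in a region did not enter the share for that region.

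The rules of comparison were set before the data were examined. A bin differed between lines where the means over cells differed by at least 0.5 copies, and where all 4 pairs of sets differed the same way by at least 0.25 copies. Regions were runs of at least 3 adjacent bins. Sets of the same line were compared by the 0.5 copies and the same minimum run. A loss was a value at or below 1.5 copies and a gain a value at or above 2.5, which here meant 1 and 3. A private chromosome change was an autosome of a cell whose mean lay at least 0.5 copies from the median of its line, over autosomes with at least 10 called bins. The distance between a pair of cells was the mean absolute difference in copy number over autosomal bins called in both, for pairs that shared at least 500. Regions named for a contrast of lines were to be the 10 highest and 10 lowest by size, and chromosomes those with a difference of at least 0.3 copies.

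Other definitions were chosen after the data were seen. A recurrent region was a run of at least 3 bins in which at least 3 cells carried the same non-2 state. An event was a run of called bins of a single non-2 state in a cell, with missing bins allowed in between, and a private event overlapped no event of the same state in any other cell. Because the rule for contrasts of lines gave no region, all regions named for the lines were chosen after their values were seen. Gene names were not used, because the gene table at hand was on another genome build than the bins.

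All 38 MCF7TR columns held only missing values, so both contrasts with MCF7TR and the side-by-side view of the MCF7M1 and MCF7TR differences could not be computed. No 2 called cells had identical columns among 1128 pairs. The rule for bins that differ was tested on simulated data with the observed missing calls kept. In the contrast of MCF7M1 with MCF7 over 5261 bins, 200 losses of 10 bins each were planted. A planted loss counted as found if any of its bins met the rule. They were found in 29.5% of cases when 40% of MCF7M1 cells carried them, in 81% at 60% of cells and in 94% at 80% of cells. Of the planted bins, 22.4%, 73.6% and 89.25% were found. All other called bins were set to 2 copies in every cell, so the 0 unplanted bins called give no rate of false calls. Planted losses kept the calls of their bins, whereas in MCF7M1 the chromosome 2 loss had 24.6% of its bins called, beside 64.8% over the autosomes. The shares found may thus be too high for losses that are seldom called. Alternatives covered the size of difference, the minimum run, medians, rescaling of each cell, filters on cells and bins, and leaving out each set. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.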

Results

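Copy number along the genome was recorded in 105 single cells of the breast cancer line MCF7 and of the lines MCF7M1 and MCF7TR. Autosomal copy numbers were present in 23 of 33 MCF7 cells (69.7%, interval 51.3 to 84.4%) and in 25 of 34 MCF7M1 cells (73.5%, interval 55.6 to 87.1%). They were present in 0 of 38 MCF7TR cells (interval up to 9.25%; 3 cells of the total would be 7.89%). These limits are not a rate of failed cells, because whether the values were lost in the cells, in the calling or in the making of the table is not given in the sources used here. A further 2 MCF7 cells had values on chromosome Y only. In cells with calls, 73.5% ± 23.2 of autosomal bins had a copy number in MCF7 (SD over cells, n = 23) and 64.8% ± 19.3 in MCF7M1 (n = 25). The range was 13.7 to 96.3% in MCF7 and 12.9 to 92.1% in MCF7M1, so the precision of a regional share varied with the number of cells called there. The read depth of the cells is unknown here.

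**Figure D1:**
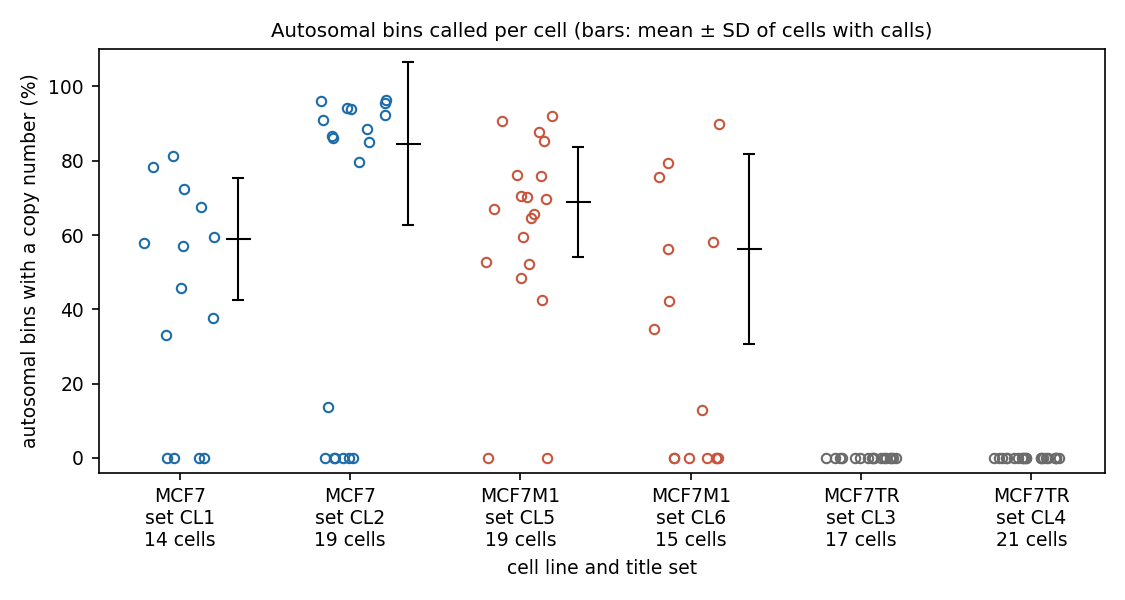
Share of autosomal 500 kb bins with a copy number (vertical axis, %) in each cell (open circles), by line and title set (horizontal axis), with the mean and SD of the cells with calls beside the points. Set CL2 of MCF7 has the highest mean (84.6%), CL6 of MCF7M1 the lowest (56.1%), and all 38 MCF7TR cells lie at 0.

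MCF7 and MCF7M1 cells shared the same clear losses, on the short-arm end of chromosome 2 and on chromosome 14. The first 15 Mb of chromosome 2 (1 to 15000000) had calls at 1 copy in all 19 MCF7 cells with at least 1 called bin there and in all 15 such MCF7M1 cells. Chromosome 14 had at least 1 bin at 1 copy between 26500001 and 41000000 in 19 of 19 called MCF7 cells and in 25 of 25 MCF7M1 cells. Between 42500001 and 48500000 the counts were 20 of 20 and 21 of 21. Most of the remaining autosomal genome was called at 2 copies in both lines. Of 174096 autosomal calls in the 48 cells, 98.4% were at 2, 1.33% at 1 and 0.229% at 3.

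On chromosome 2, all 352 calls of MCF7 and all 178 calls of MCF7M1 in the lost region were at 1 copy. The exact intervals for the share of called cells were 82.4 to 100% in MCF7 and 78.2 to 100% in MCF7M1. Only 52.8% of the region's bins were called in MCF7 and 24.6% in MCF7M1, so 4 MCF7 cells and 10 MCF7M1 cells with calls elsewhere could not be read there. Its last bins, from 12500001 to 15000000, rested on 2 MCF7 cells and on 1 or 2 MCF7M1 cells. On chromosome 14, all 22 MCF7 cells with a call in the 2 blocks (interval 84.6 to 100%) and all 25 MCF7M1 cells (interval 86.3 to 100%) had at least 1 of these bins at 1 copy. In the block from 26500001, 2 cells of each line also had calls at 2 copies, all of them before 28000001. In MCF7, only the losses of cells 16, 17, 20, 24 and 32 began before 28000001. In MCF7M1, only that of cell 30 did, with 9 called bins from 19000001 to 47000000. The shared loss is thus shown from 28000001 and not from 26500001. Between the blocks no MCF7M1 cell and only a single MCF7 cell had a call. This was cell 32, which was at 1 copy there, so the data do not show whether the loss runs through the gap in other cells. Over both lines, 59 autosomal bins with at least 10 called cells were never called at 2 copies, and all of them lay on chromosome 2 from 1 to 12000000 or on chromosome 14 from 28000001 to 48500000.

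**Figure D2:**
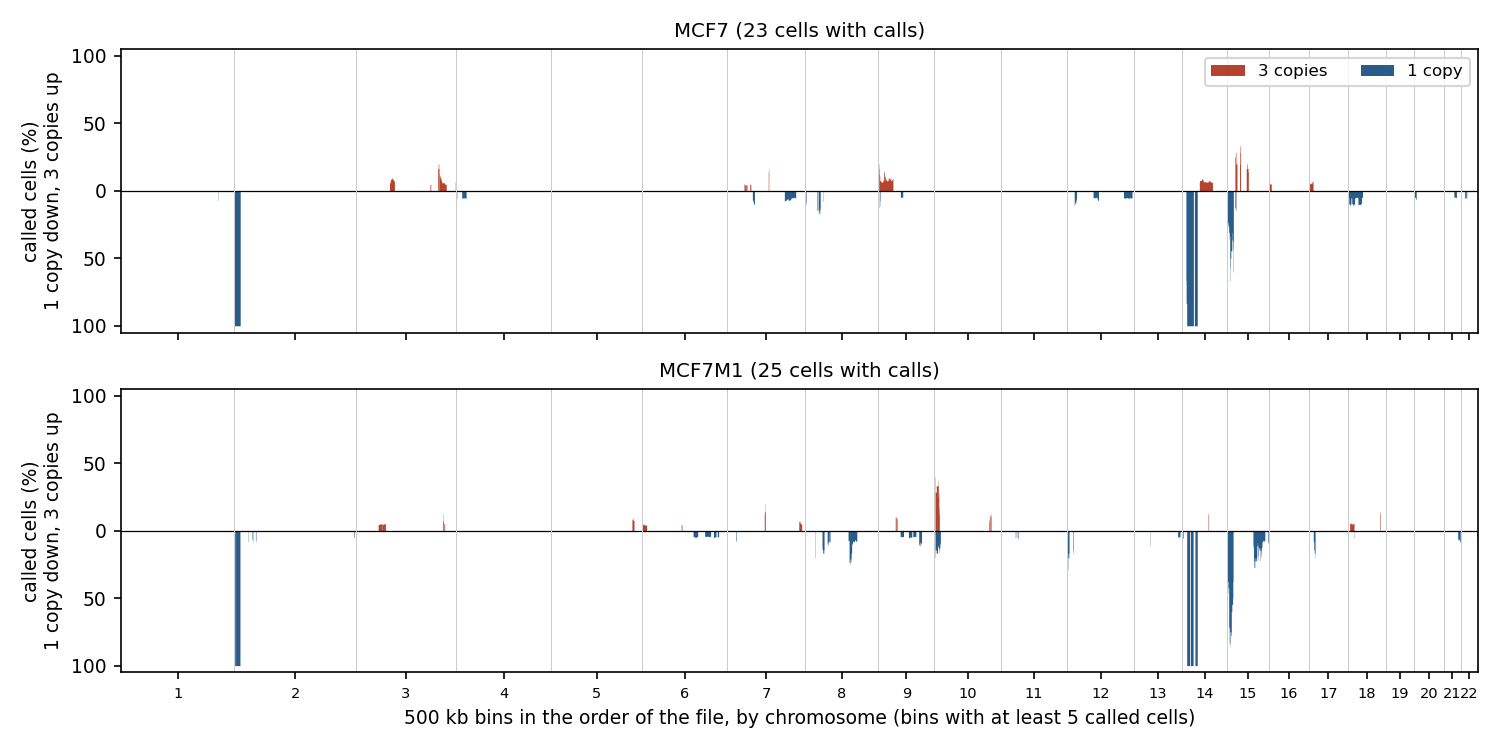
Share of called cells at 3 copies (red, upward) and at 1 copy (blue, downward), in % of the cells called in each 500 kb bin, along the autosomes in MCF7 (top) and MCF7M1 (bottom), for bins with at least 5 called cells. The losses of chromosomes 2 and 14 reach 100% in both lines, and the loss on chromosome 15 from 20000001 to 33000000 is the next most frequent.

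The contrast of MCF7M1 with MCF7 asked which parts of the genome changed copy number between those lines. No region differed: 0 of 4855 autosomal bins called in all 4 sets met the rule. The mean copy number was identical in 83.6% of the 4955 bins with at least 5 called cells per line, and the largest difference among them was 0.476 copies, on chromosome 15 from 25000001 to 25500000. There, 5 of 14 called MCF7 cells and 5 of 6 called MCF7M1 cells were at 1 copy. Between the sets of a line, where the rule demands no second pair of sets, 20 bins differed in MCF7, mainly on chromosome 3 from 70000001 to 76000000, and 10 in MCF7M1, on chromosomes 10 and 15. By line means alone, 4 bins of chromosome 15 differed between the lines, and with at least 5 called cells on each side all 3 counts were 0. Without set CL2, 17 bins were lower in MCF7M1, on chromosome 3 from 70000001 to 76000000 and chromosome 15 from 59000001 to 61500000. Without CL5, 3 bins of chromosome 10 (6500001 to 8000000) were higher and 3 of chromosome 15 (73000001 to 74500000) lower, and without CL6, 4 bins of chromosome 15 (24000001 to 26000000) were lower. All MCF7 cells lay in one index series and all MCF7M1 cells in the other, so line and index series cannot be told apart.

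Losses on chromosome 15 from 20000001 to 33000000 were the most frequent changes carried by part of the cells. In this region, 5 of 21 called MCF7 cells (23.8%, interval 8.22 to 47.2%) and 8 of 19 called MCF7M1 cells (42.1%, interval 20.3 to 66.5%) had bins at 1 copy. By set these were 1 of 8 cells in CL1, 4 of 13 in CL2, 6 of 13 in CL5 and 2 of 6 in CL6, so the MCF7 share was 12.5% without CL2. The remaining recurrent regions were found in MCF7M1 alone, at shares whose intervals overlapped those of MCF7. Chromosome 8 from 88500001 to 92500000 was lost in 4 of 17 called MCF7M1 cells (23.5%, interval 6.81 to 49.9%), all of set CL5, and in 0 of 17 MCF7 cells (interval up to 19.5%). Chromosome 15 from 72000001 to 74500000 was lost in 3 of 15 MCF7M1 cells (20%, interval 4.33 to 48.1%) and likewise in 0 of 17 MCF7 cells. A gain of chromosome 10 from 6500001 to 8000000 was called in 3 of 10 MCF7M1 cells (30%, interval 6.67 to 65.2%) and in 0 of 8 MCF7 cells (interval up to 36.9%). No test between the lines was run on these 4 regions, and none met the rule for bins that differ while all sets were kept.

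**Figure D3:**
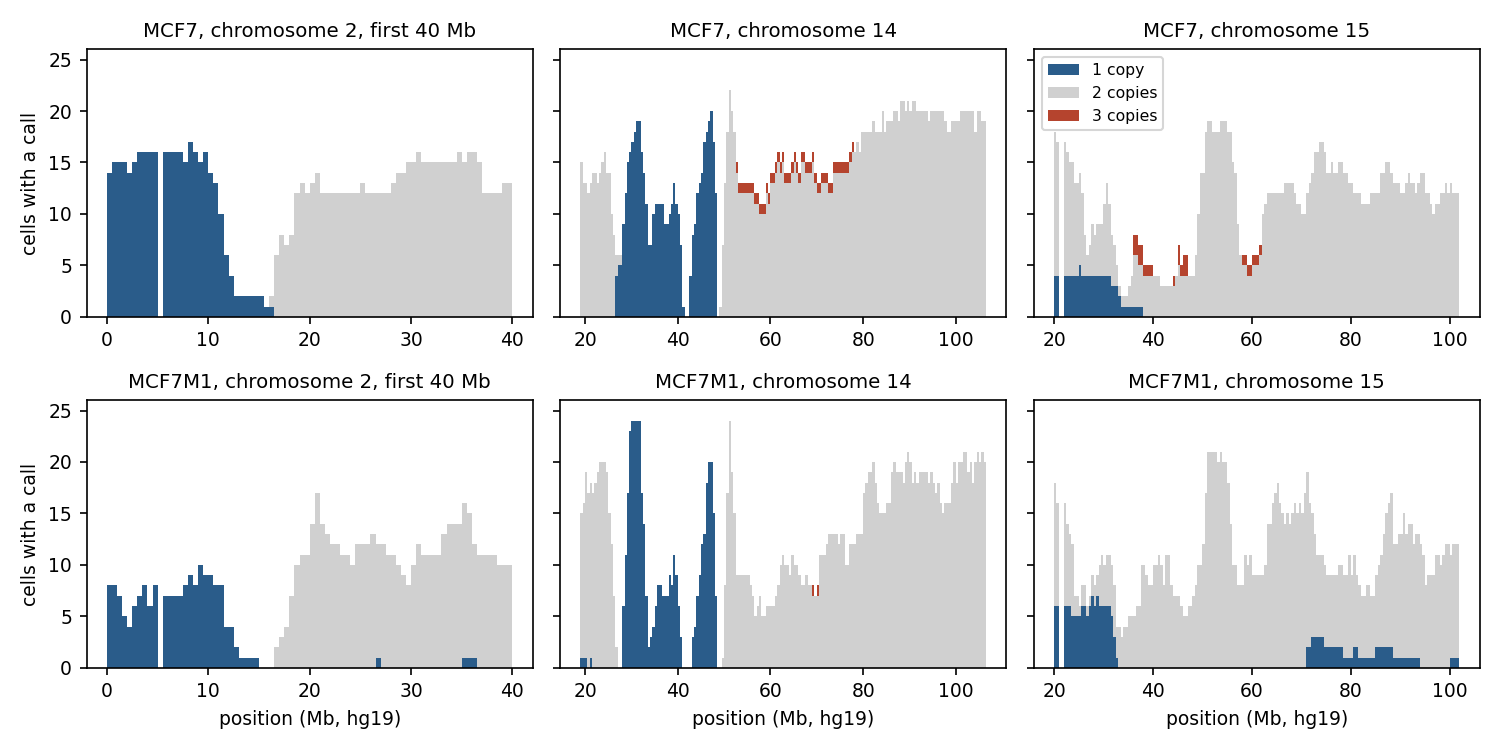
Number of cells (vertical axis) called at 1 (blue), 2 (grey) and 3 copies (red) in each 500 kb bin along the first 40 Mb of chromosome 2 and along chromosomes 14 and 15 (horizontal axis, Mb), stacked, in MCF7 (top) and MCF7M1 (bottom). On chromosomes 2 and 14 the lost blocks hold almost no cell at 2 copies. On chromosome 15 from 20000001 to 33000000, cells at 1 and at 2 copies lie side by side.

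Whole chromosomes were within 0.122 copies of each other between the lines. The mean copy number of chromosome 14 was 1.87 ± 0.202 in MCF7 (SD over 23 cells) and 1.82 ± 0.0580 in MCF7M1 (25 cells). Chromosome 2 averaged 1.96 ± 0.0249 and 1.98 ± 0.0215, and chromosome 15 averaged 1.997 ± 0.176 in 22 MCF7 cells and 1.87 ± 0.253 in 25 MCF7M1 cells. Chromosome 15 had the largest difference of the 22 autosomes. It was lower in MCF7M1 in all 4 pairs of sets, with differences of -0.04998 to -0.18998 copies, whereas CL2 minus CL1 was -0.0845 copies and CL6 minus CL5 was 0.0555. The median over cells was 2 copies in both lines, so the difference in means rests on few cells. Among them were MCF7 cell 14 at 2.67 copies, on 12 of 162 bins, and MCF7M1 cells 5 and 16 at 1 and 1.22 copies. No autosome reached 0.3 copies. Chromosome 19 was at 2 copies in every call of both lines, and it was the only autosome without a gain or a loss in any cell. Between the sets of a line the largest difference was 0.101 copies in MCF7, on chromosome 18, and 0.0690 in MCF7M1, on chromosome 10.

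Few of the called autosomal bins were at a copy number other than 2 in either line. MCF7 is known as an aneuploid line, and the baseline of the calls is not given in the sources used here, so these shares count departures from the called state 2 and not from a diploid genome. They also leave out the missing bins, 31.1% of autosomal bins in called cells, which lay at 504 of the 560 edges of altered stretches. Losses covered 1.22% ± 0.7996 of the called autosomal bins of a cell in MCF7 and 1.21% ± 0.863 in MCF7M1, and gains covered 0.269% ± 0.498 and 0.187% ± 0.338. Both together came to 1.49% ± 1.03 in MCF7 (n = 23) and 1.40% ± 0.9495 in MCF7M1 (n = 25). The share fell to 0.542% in MCF7 and 0.524% in MCF7M1 over bins called in at least 80% of the cells of both lines. No bin of the chromosome 2 loss passed this filter, as at most 17 of 23 MCF7 cells were called in any of them. The fall was thus partly fixed by the filter. All 48 cells had at least 1 loss. Gains were present in 11 of 23 MCF7 cells (47.8%, interval 26.8 to 69.4%) and in 9 of 25 MCF7M1 cells (36%, interval 18 to 57.5%). By set the MCF7 share was 30% in CL1 and 61.5% in CL2, so without CL2 it lay below that of MCF7M1. Within MCF7 the altered share was 0.786% ± 0.470 in set CL1 and 2.03% ± 1.03 in set CL2, a wider gap than between the lines, and without CL2 the share was lower in MCF7 than in MCF7M1. Within each line the better called set had the higher share. CL2 and CL5, with means of 84.6% and 68.9% of bins called, had 2.03% and 1.54% altered. CL1 and CL6, with 59.0% and 56.1% called, had 0.786% and 1.09%, so between CL1 and CL6 the order was the other way. Differences in this share thus cannot be told apart from differences in call rate.

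Single cells of both lines stood apart from their line in the mean of a chromosome over its called bins. By the rule for private chromosome changes, 5 of 23 MCF7 cells (21.7%, interval 7.46 to 43.7%) and 3 of 25 MCF7M1 cells (12%, interval 2.55 to 31.2%) carried at least 1. In MCF7 these were chromosome 18 at means of 1.25 and 1.44 copies in cells 31 and 16, chromosome 14 at 2.73 in cell 33, chromosome 15 at 2.67 in cell 14 and chromosome 9 at 1.37 in cell 4. In MCF7M1 they were chromosome 15 at 1 and 1.22 copies in cells 5 and 16 and chromosome 10 at 1.15 in cell 17. These means cover called bins only. The rule compares a cell with the median of its line and does not ask whether other cells carry the change. The chromosome 15 losses of MCF7M1 cells 5 and 16 overlapped the recurrent loss of that chromosome from 20000001 to 33000000. The chromosome 18 losses of MCF7 cells 16 and 31 overlapped each other. Only the chromosome 10 loss of MCF7M1 cell 17 and the chromosome 15 gain of MCF7 cell 14 overlapped no event of the same state in another cell. The altered stretches ranged from 4 Mb of chromosome 15 in MCF7 cell 14 and 11.5 Mb of chromosome 10 in MCF7M1 cell 17 to 61.5 Mb of chromosome 15 in MCF7M1 cell 5 and 75.5 Mb of chromosome 9 in MCF7 cell 4, the last 2 with most bins missing in between. Several rested on few bins: MCF7 cell 4 had 19 of 218 bins of chromosome 9 called, MCF7 cell 14 had 12 of 162 bins of chromosome 15, MCF7M1 cell 5 had 24 of those 162 bins, and MCF7M1 cell 17 had 27 of 257 bins of chromosome 10. All 3 MCF7M1 cells were of set CL5, and without that set the MCF7M1 share was 0. With a limit of 0.3 copies the shares were 26.1% in MCF7 and 28% in MCF7M1.

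Over all cells with calls, pairs within a line and between lines lay at similar mean distances. The distance between a pair of cells averaged 0.0103 ± 0.0110 copies per bin within MCF7 (250 pairs), 0.00974 ± 0.0126 within MCF7M1 (294 pairs) and 0.01004 ± 0.0109 between the lines (563 pairs). This rested on the mix of sets: without CL2 the values were 0.00456 within MCF7, 0.00974 within MCF7M1 and 0.00675 between the lines, and without CL1 they were 0.0156, 0.00974 and 0.0126. The score for a nearest other cell of the same line averaged 48.6% over the 48 cells (interval 33.3 to 62.8%), where the numbers of cells alone give 49.2%. With the cell's own set left out, the average was 34.9% (interval 22.2 to 50.5%) beside 31.1% from numbers alone. Neither average is a whole number of cells. Their intervals are thus approximate, and they treat the cells as independent although neighbours are shared. By this measure the nearest cells did not separate MCF7 from MCF7M1.

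MCF7TR gave no copy number in any bin of any chromosome, in 17 cells of set CL3 and 21 cells of set CL4. The gains and losses of MCF7TR against MCF7 and against MCF7M1 are therefore not analysed here, and neither is the overlap of its changes with those of MCF7M1.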

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

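All tests in this part were chosen after the results were seen. Chromosome X, which no comparison used, was called at 1 copy in 98.4% of MCF7 calls and in every MCF7M1 call. MCF7 cell 2 departed from this with 76 X bins at 2 copies, from 8000001 to 20500000 and from 24000001 to 49500000. MCF7 cell 20 had 4 X bins at 0 copies, from 72000001 to 74000000.

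The absence of calls in MCF7TR was complete in both index series. A failed index series is argued against as the whole cause, because at least 69.7% of the MCF7 or MCF7M1 cells had calls in each series that also held MCF7TR cells. Low usable coverage of the MCF7TR cells cannot be told apart from a genome that the caller could not fit, since a depth was given for 0 of these cells. A step in the making of the table that left these columns empty stays open as well, and was not tested. A drug-tolerant state with many more copy-number changes may be a biological explanation, and it stayed untested.

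The losses of chromosomes 2 and 14 were in both lines. GC content or mappability is argued against: bins of other autosomes matched on both were at 1 copy in 0.498% of calls, beside 99.6% in the lost regions. A loss brought in by a single set of cells is argued against too, since the lowest share of cells with the chromosome 14 loss in any of the 4 called sets was 90% (CL1, where the only cell without the loss had no call in the region). The chromosome 2 loss was seen in all 4 sets too, but in only 50% of the cells of CL6 and 64.7% of those of CL5, the others having no call there. A baseline that the caller used for all cells was not tested and stays open. Losses that MCF7 and MCF7M1 hold from common ancestor cells are a biological hypothesis that these data do not test.

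Fewer bins were called in MCF7M1 than in MCF7, by 8.66 percentage points, but the order rests on set CL2: the mean was 59.0% in CL1 and 84.6% in CL2, beside 64.8% in MCF7M1. Differences between sets of cells within a line are a candidate explanation, because the sets of MCF7M1 differed by 12.7 points and those of MCF7 by 25.6. Whether the index series matters cannot be told apart from the lines, as 0 cells of MCF7TR, the line in both series, had calls. A biological difference between the lines stays open and untested.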

How the results depend on the processing

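The tests with a minimum of 5 called cells, with line means alone and with cells that had at least 50% of bins called were chosen after the results were seen, as were those with bins called in at least 80% of cells and with missing bins at 2. Over all alternatives 153 values stayed within their SD, interval or 1.5 times their count, and 26 did not. The SDs are those of single cells or pairs, so large shifts of a mean stayed within them. One such shift was the MCF7 altered share without CL2. The count of 153 thus says little about how stable the means are. The order of the lines turned in several. The altered share, higher in MCF7 as reported, was 0.786% in MCF7 against 1.40% without CL2, and 1.49% against 1.54% in MCF7M1 without CL6. It was 0.542% and 0.524% over bins called in at least 80% of cells, and 1.22% and 0.944% with missing bins at 2. Values that stayed include those of settings that cannot act on whole copy numbers (rounding, the cap at 8 copies, loss and gain limits of 1.0 and 3.0, and the noise filter, which removed 0 cells). They also include values of a single line when a set of the other line was left out, which cannot change. The count of 0 bins between MCF7M1 and MCF7 held under each planned setting that kept all sets. It ranged from 0 to 17 when a set was left out (17 without CL2, 6 without CL5 and 4 without CL6), and was 4 with line means alone (chromosome 15, 33000001 to 35000000, 0.542 copies higher in MCF7M1). Leaving out a set drops the demand that its pairs go the same way.

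Bins that differed between the sets of MCF7, 20 as reported, came to 4 at 1.0 copies, 33 at 0.3 copies, 12 in runs of at least 10 bins, 7 with each cell rescaled to a mean of 2, 6 without the most variable bins and 0 with at least 5 called cells. Between the sets of MCF7M1, 10 as reported, they came to 0 at 1.0 copies, 23 at 0.3 copies, 0 in runs of at least 10 bins, 25 with medians over cells, 3 rescaled, 0 without the most variable bins, 0 with at least 5 called cells and 0 in cells with at least 50% of bins called. These bins thus rested on few cells. As 1 minus the correlation, another unit, distances were 0.359 within MCF7, 0.368 within MCF7M1 and 0.385 between them, which turned the order within the lines, as did leaving out CL2 (0.00456 in MCF7, 0.00974 in MCF7M1) or CL6 (0.0103, 0.0105). Private chromosome changes were found in 0% of MCF7 and 4% of MCF7M1 cells at 1.0 copies, in 26.1% and 28% at 0.3 copies, and in 0 to 17.6% of MCF7M1 cells with a set left out. Medians over bins gave 2 copies for chromosome 2 in both lines and for chromosome 14 in MCF7M1, because the losses cover a minor part of each chromosome.

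Alternatives for MCF7TR were not run, since no cell had a call. No paired analysis was possible because the numbers in the titles name single cells and no test was run.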

Other observations

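All observations in this part were chosen after the data were seen, and none was tested. Single cells carried large changes outside the recurrent regions. The positions give the first and last called bin of a stretch, and bins in between may be missing. In MCF7M1 cell 12, calls covered 28 of 49.5 Mb of the chromosome 6 loss and 24.5 of 42.5 Mb of the chromosome 9 loss. In MCF7 cell 33 they covered 10.5 of 21 Mb of the chromosome 4 loss. MCF7M1 cell 12 was at 1 copy on chromosome 6 from 103500001 to 153000000 and on chromosome 9 from 72500001 to 115000000, and at 3 copies on chromosome 6 from 500001 to 9500000. MCF7 cell 33 was at 3 copies on chromosome 14 from 52500001 to 78000000, on chromosome 17 from 500001 to 9000000 and on chromosome 16 from 500001 to 5000000. The same cell was at 1 copy on chromosome 7 from 116000001 to 138500000 and on chromosome 4 from 1 to 21000000. MCF7 cell 17 had lost chromosome 12 from 54000001 to 64500000 and from 113000001 to 129500000. Chromosome 9 was at 3 copies from 1 to 28500000 in MCF7 cell 21, and chromosome 18 at 1 copy from 1 to 32000000 in MCF7 cell 31. MCF7M1 cell 20 had gained chromosome 3 from 44000001 to 58000000, and MCF7M1 cell 11 had gained chromosome 18 from 3500001 to 12000000.

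The start of chromosome 10 was called both ways in MCF7M1. Cells 5 and 16 were at 3 copies from 500001 to 10000000 and to 9500000, whereas cell 17 was at 1 copy from 500001 to 12000000. MCF7M1 cell 34 was also at 3 copies, from 6500001 to 8000000. No MCF7 cell had a call other than 2 on chromosome 10, but only 8 of 23 MCF7 cells were called from 6500001 to 8000000.

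Losses found in a single cell and in no other were present in 6 of 23 MCF7 cells (26.1%, interval 10.2 to 48.4%) and in 13 of 25 MCF7M1 cells (52%, interval 31.3 to 72.2%). By set the counts were 1 of 10 cells in CL1, 5 of 13 in CL2, 8 of 17 in CL5 and 5 of 8 in CL6. The intervals of the lines overlapped, and the sets of MCF7 were as far apart as the lines. Many of the MCF7M1 cells counted through very short losses only. These had 4 called bins in cells 21, 23 and 34, at most 3 in cell 2, 2 in cells 13 and 30, and 1 in cell 22. In MCF7, cell 32 alone counted through so few, with 1 called bin. The higher share in MCF7M1 thus rests on short calls. Gains found in a single cell were present in 6 MCF7 cells and in 5 MCF7M1 cells.

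No altered stretch touched a bin called at another copy number. The 280 unbroken stretches at 1 or 3 copies had 560 edges. Of these, 504 lay next to a missing bin, 56 at the first or last bin of a chromosome in the data and 0 next to another call. By comparison, 31.1% of autosomal bins were missing in these cells. The breakpoints of the changes named above are therefore known only to within the missing bins around them.

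Chromosomes that were hard to call in MCF7 were hard to call in MCF7M1. Chromosome 8 had 43.4% of its bins called in MCF7 and 35.3% in MCF7M1, and chromosome 15 had 47.4% and 44%, beside 84.4% and 81.4% for chromosome 1. Across the 22 autosomes the call rates of the lines had a Pearson correlation of 0.927, and chromosome 6 was the only autosome not called less in MCF7M1. Across 5261 bins, which are not independent, the share of cells called had a Pearson correlation of -0.000816 and a Spearman correlation of -0.109 with GC content, and of -0.00483 and -0.0262 with mappability.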
